A study of Caenorhabditis elegans with 2 samples.

How the data were processed

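Chromatin immunoprecipitation sequencing (ChIP-seq) of HIM-1 fused to eGFP was carried out on whole Caenorhabditis elegans hermaphrodites at the L4/young adult stage, 51 hours after synchronization as starved L1 larvae. Both samples belonged to 1 group and were numbered as biological replicates 1 and 2 in the labels. The labels' free text named an anti-GFP antibody, while their antibody field named him-1. There was no second condition, and no untagged or GFP-only immunoprecipitation was analysed here.

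The files used were narrowPeak lists of peaks, 4 in the ce11 build and 4 in ce10, per the text deposited with each sample. In each build there was a list for each replicate and a pooled list from both replicates' alignments together, all called against the same control and holding peaks and background entries as input to the irreproducible discovery rate (IDR) procedure, and an optimal list thresholded by IDR, per the same deposited text. The signal value of each peak is the authors' own value from their caller, and its scale is not given in the sources used here. The deposited −log10 q-value of each peak was read only to describe the lists. The aligner, the peak caller and their versions are not given in the sources used here. Alignments, coverage tracks and the control were not used here. The lists give no read counts, so the depth of each library is unknown, and no value below could be adjusted for it.

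The 1797 optimal peaks in ce11 were the 1797 entries with the highest signal value among the 12228 entries of the pooled list, and each overlapped an entry in both replicates' lists. The pooled signal was close to the sum of both replicates' signals, with a median ratio of 1.00 for the sum over the pooled value. The replicate 1 signal was higher than that of replicate 2 by a median factor of 1.42, so signal values were compared only within a list. A total of 1284 optimal peaks shared the highest −log10 q-value, 3.41, so q-values could not rank them and peaks were ranked by signal value. A total of 111 neighbouring optimal peaks overlapped each other. Because both replicates were called against the same control, part of their overlap can come from that control.

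Peaks were placed by their summits. Gene positions came from Ensembl release 115 (WBcel235, the assembly also called ce11), and sequence and tRNA isotypes came from the RefSeq copy of the same assembly. Only ce11 lists were set against genes or sequence. No coordinates were converted between builds, and the ce10 lists, which served as an alternative for results that need no genes, were divided by the WBcel235 chromosome lengths. A promoter peak had its summit within 500 bp of the 5' end of a protein-coding transcript. Other summits were assigned to coding sequence, UTR, intron or intergenic sequence, in that order. These features were those of protein-coding genes, so intergenic sequence included non-coding RNA genes outside them. A non-coding RNA gene had a peak when a summit lay within 250 bp of it. Motifs were searched on both strands within 100 bp of the summit.

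Random expectation came from 1000 circular shifts of all summits within their chromosomes, which keep the spacing of peaks. The smallest p these can give is 0.001 one-sided and 0.002 two-sided. Densities on X and autosomes, and in chromosome centres (the middle 50% of the length) and outer parts (25% at each end), were compared by a two-sided permutation test with 100000 permutations of 500 kb bins, with a smallest p of 1e-05. Intervals of X to autosome ratios came from 1000 bootstrap draws of the same bins. Gene lists were compared with all other protein-coding genes by a two-sided Fisher's exact test, and beside it by the shifts. Adjusted p-values are Benjamini-Hochberg values over 20 gene lists, 5 gene features, 4 classes of non-coding RNA genes, or 9 sequence tests (8 motifs and GC percent), with a threshold of 0.05. Intervals of shares are Wilson 95% intervals and cover counting error only. These tests treat genomic positions, bins or genes as units, so their p-values do not measure the spread between worm cultures. Correlation intervals came from 1000 bootstrap draws of 1 Mb blocks. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

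The main tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. Further tests chosen after seeing the data are named as such where they are reported. The rule took the 25 optimal peaks with the highest signal with the protein-coding gene whose 5' end is nearest, the 5 highest peaks on X, up to 4 members of each gene list with the highest promoter peak, every cohesin gene, him-1 and unc-119, and the 3 genes with the highest peak in each class of non-coding RNA genes. The nearest gene is a label of position only. A gene that the rule names in the chemoreceptor list is not reported here. The lists held cohesin, condensin and dosage compensation, meiosis, germline development, cell cycle, ribosomal protein, translation factor, proteasome, histone, heat shock, respiratory chain, intestine, muscle, collagen, neuron, major sperm protein, chemoreceptor, nuclear hormone receptor, homeobox and splicing genes. The symbols coh-2, pqn-85, rad-54 and sap-1 were not matched to a protein-coding gene of the annotation and were left out.

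The procedures were tested on simulated peak sets. With summits shifted or bins shuffled so that no effect was present, 0.75% to 5% of tests had an unadjusted p under 0.05, and Fisher's exact test on gene lists did so in 3.25% of 400 tests. Planted effects were recovered in 20 of 20 sets for each of promoters, tRNA genes, ribosomal protein genes, GAGA repeats, X density, centre density and shared peaks. Planted were 200 promoter summits, 50 at tRNA genes or GAGA repeats and 20 at ribosomal protein genes. Densities were planted at 1.5 times and shared peaks at 50%. Shared peaks were checked only by their overlap share, without the shift test, so that recovery says nothing about the test. Ribosomal protein genes were checked by Fisher's exact test only. The density sets placed positions independently, and 1.5 exceeds the X ratio of 1.36 reported below, so power for that ratio was not shown. Sets without an effect came from shifts or shuffles like those of the tests, so their rates check the procedure only. A first run of the GAGA repeat simulation with 200 shifts recovered none, because the smallest p of 200 shifts stays above 0.05 after adjustment when a single one of 9 tests reaches it, and it was repeated with 1000.

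Alternatives covered the stricter part of the optimal list, each replicate's own list, the ce10 lists, other windows, bins and overlaps, uniform placement and another gene background. A further 4 alternatives were chosen after seeing the data: GC-matched random positions for motifs, X density without peaks near tRNA genes, gene lists without peaks near tRNA or snoRNA genes, and only non-coding RNA genes whose sequence occurs once.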

Results

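Peaks of ChIP-seq against eGFP-tagged HIM-1, the SMC1 subunit of the cohesin complex that holds sister chromatids together, were analysed in whole C. elegans hermaphrodites of 1 group with 2 replicates. The deposited optimal list held 1797 peaks in ce11, with signal values from 102.0 to 1042 and a median of 144. The replicates' own lists, which include background entries, held 16213 and 15469 entries. Signal values are the authors', and read depth is unknown.

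Most of the sites with high signal were shared by both replicates. Of the 1797 entries with the highest signal in replicate 1, 1421 (79.1%, 95% interval 77.1 to 80.9) overlapped such an entry of replicate 2 by at least 1 bp, and 75.0% did so in the other direction. Circular shifts gave a mean of 1.68% and at most 3.06% (permutation p = 0.001, one-sided, the smallest the shifts can give). Across the 1797 optimal peaks, which are not independent replicates, Spearman's rho of the replicates' log2 signals was 0.635 (95% bootstrap interval 0.603 to 0.664) and Pearson's r was 0.698 (0.666 to 0.729). The peaks had been selected for high pooled signal, and both replicates shared a control.

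**Figure D1:**
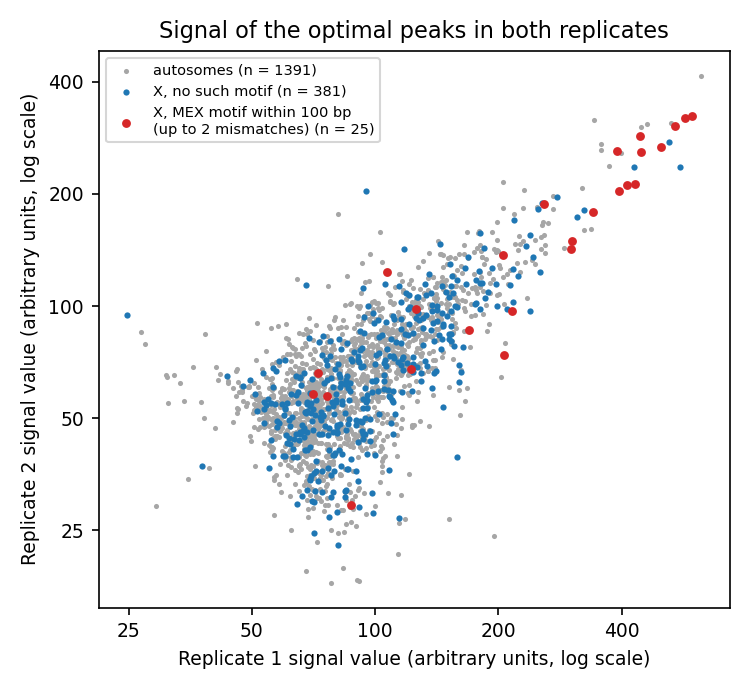
Signal value in replicate 1 (x axis) and replicate 2 (y axis), in arbitrary units on log scales, for the 1797 optimal peaks, 1 point per peak. The 25 peaks on X with the MEX motif within 100 bp (red, up to 2 mismatches; marked after seeing the data) had a median pooled signal of 447, against 150.2 for other X peaks (blue).

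The highest peaks included promoters of ribosomal protein genes on autosomes and sites away from promoters on X. The highest of all, at III:3867422-3867738 (ce11), had its summit 285 bp upstream of rpl-3, a large-subunit ribosomal protein gene, with a signal of 1042 (625 in replicate 1 and 414 in replicate 2). The promoters of rpl-15 (IV:654747-655075, signal 842), cdc-48.1 (II:10563421-10563686, signal 771), which encodes the AAA ATPase p97, and rpl-35 (III:7854587-7854841, signal 756) were among the 10 highest. Of the 25 highest peaks, 15 were on X, and none of those 15 was a promoter peak, while 7 of the 10 autosomal ones were.

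The 5 highest X peaks had signals of 790 to 909. The strongest, at X:6296296-6296816 (signal 909), lay in an intron of mom-1, a Wnt pathway gene, and 3353 bp upstream of the nearest protein-coding 5' end, that of cest-16. The next, at X:11093921-11094384 (signal 882), was intergenic, with the nearest 5' end at W02H3.3. Intergenic peaks also lay nearest F20B6.9 (X:4209032-4209468, signal 836), K02D3.1 (X:13700669-13701099, signal 794) and ZK899.6 (X:9465660-9466069, signal 790). An intergenic peak at X:8036206-8036676 (signal 766) lay 4893 bp upstream of xol-1, the switch gene of sex determination and dosage compensation. The other X peaks among the 25 lay nearest nspc-17, Y41G9A.17, gtr-1, F19H6.5, T27A8.7, F55G7.5, F22H10.2, C41A3.2 and ftt-2, with signals of 496 to 712. The C41A3.2 peak, at X:5429453-5429630, lay in coding sequence of pks-1 and was 15197 bp from that 5' end. On autosomes the remaining peaks lay nearest tasp-1, ZK1248.17, cmd-1 (calmodulin), egg-5, Y17G9B.5 and ska-3, with signals of 526 to 659. The Y17G9B.5 peak was also the promoter peak of rpl-20, and the ska-3 promoter peak lay within 250 bp of the snoRNA gene F54E7.10. The peaks nearest ZK1248.17 and egg-5 lay within 250 bp of sls-2.1 and sls-2.4, genes of the SL2 spliced leader RNA used in trans-splicing.

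X carried more peaks per Mb than the autosomes combined. It held 406 peaks, or 22.9 per Mb, against 16.8 per Mb on autosomes, a ratio of 1.36 (95% bootstrap interval 1.21 to 1.55; permutation p = 0.00387 over 500 kb bins). Chromosomes I and III, at 22.1 and 21.9 per Mb, were close to X, whereas V had 11.5 per Mb. Per protein-coding gene, the ratio of X to autosomes was 1.84 (1.62 to 2.13; permutation p = 1e-05, the smallest the permutations can give). Without the peaks within 250 bp of a tRNA gene, a comparison chosen after seeing the data, the ratio was 1.19 (1.02 to 1.38) and no longer passed the test (permutation p = 0.124). With the 6 chromosomes as units, X ranked highest, for which the smallest one-sided p is 0.167.

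**Figure D2:**
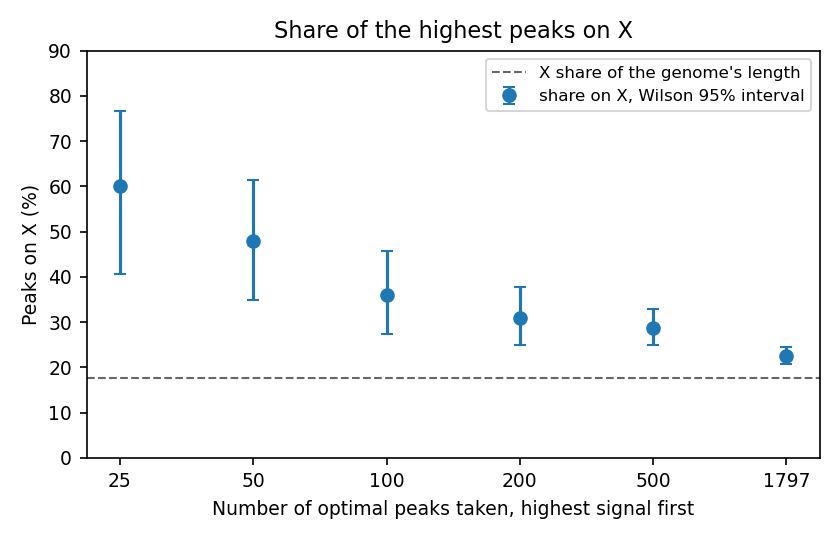
Share of peaks on X (y axis, %) among the optimal peaks with the highest signal (x axis, number taken), with Wilson 95% intervals; the dashed line is the share of X in the genome's length, 17.7%. The share was 60% of the highest 25, 36% of the highest 100 and 22.6% of all 1797.

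The typical signal of X peaks was little above that of autosomal peaks, while X held a large share of the top of the list. The median log2 signal of peaks was 7.26 on X and 7.16 on autosomes, a difference of 0.10. The permutation test compared medians of bins instead, whose difference is not given here, and did not pass (p = 0.435). X contributed 15 of the 25 highest peaks (60%, 95% interval 40.7 to 76.6), 15 in replicate 1's own list and 13 in that of replicate 2, against 17.7% of the genome's length. Among the stricter part of the list the difference of peak medians was 0.16, and the test of bin medians passed (permutation p = 0.00407). That test also passed for replicate 2 alone (peak difference 0.11, permutation p = 0.0425). With 1 Mb bins it passed too (peak difference 0.10, permutation p = 0.0494). It did not pass for replicate 1 alone (peak difference 0.10, permutation p = 0.0595) or for the ce10 lists (peak difference 0.09, permutation p = 0.776).

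Per Mb, autosomal peaks were concentrated in the gene-dense chromosome centres, while X peaks were not. The middle 50% of chromosome length held 21.8 peaks per Mb and the outer 25% at each end 14.1, a ratio of 1.55 (permutation p = 1e-05, the smallest the permutations can give). The ratio was 2.44 on V, 1.93 on II, 1.75 on I, 1.70 on III and 1.43 on IV, and 0.952 on X, where it was 0.756 among the stricter part of the peaks (10.8 against 14.3 per Mb) and 1.04 without replicate 1; whether X differs from the autosomes in this ratio was not tested. Per protein-coding gene the ratio over all chromosomes was 1.25 (permutation p = 0.00418), with 2.21 on V, 1.79 on II, 1.27 on I and 1.17 on III, while it was 0.977 on IV and 0.846 on X.

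**Figure D3:**
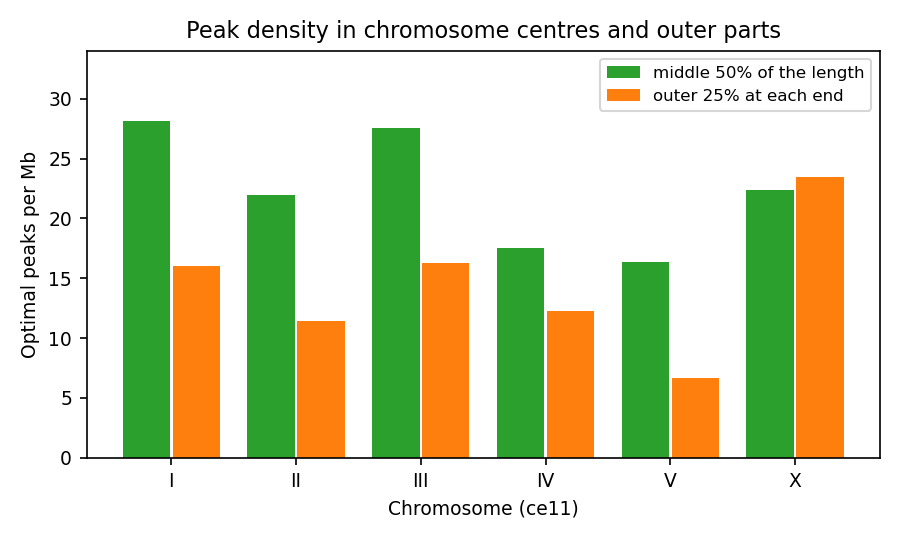
Optimal peaks per Mb (y axis) in the middle 50% (green) and the outer 25% at each end (orange) of each chromosome (x axis, ce11); bars are counts divided by length, with no replicate error. Centres exceeded outer parts per Mb on the 5 autosomes, from 1.43-fold on IV to 2.44-fold on V, and the ratio was 0.952 on X.

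HIM-1 peaks favoured promoters and avoided coding sequence. Promoters held 763 of the 1797 summits (42.5%, 95% interval 40.2 to 44.8), against a mean of 22.5% in circular shifts. Intergenic sequence held 35.8% against 29.7%, introns 18.8% against 26.9%, UTRs 1.5% against 3.02% and coding sequence 1.45% against 17.9%. Each of the 5 shares had an adjusted permutation p of 0.002, the smallest the shifts can give. Intergenic here means outside protein-coding genes and includes non-coding RNA genes. Of the 1797 summits of any feature, 206 (11.5%) lay within 250 bp of a tRNA or snoRNA gene. With a 250 bp window the promoter share was 28.3% against 11.9%. Of the promoter summits, 672 (88.1%) lay upstream of the nearest 5' end, and the median position of all promoter summits relative to it was -167 bp. On X, promoters held 33.5% and intergenic sequence 45.3%, against 45.1% and 33.1% on autosomes; the difference was not tested.

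Genes of small structural RNAs carried many peaks. A summit lay within 250 bp of 147 of 612 tRNA genes (24.0%, 95% interval 20.8 to 27.6), 68 of 346 snoRNA genes (19.7%, 15.8 to 24.2) and 12 of 129 snRNA genes (9.30%, 5.40 to 15.6). Circular shifts gave means of 1.09%, 1.13% and 0.912% (adjusted permutation p = 0.00266 for each class). Summits rarely lay inside the snoRNA genes (6 of 346, 1.73%) or snRNA genes (2 of 129, 1.55%), and lay inside 72 of the tRNA genes (11.8%). Each of these classes still exceeded the mean of the shifts and passed the test. For snRNA genes this rested on 2 genes (adjusted permutation p = 0.04), and the highest shift reached 5. Among the stricter part of the peaks the tRNA share was 14.2%. With all peaks, it was 15% for tRNA genes whose sequence occurs once, a comparison chosen after seeing the data. None of 20 rRNA genes had a peak (adjusted permutation p = 1), a share of up to 16.1% by its 95% interval. Shifts gave a mean of 1.49%, too low for a depletion to be seen, and only 5 of these genes have a sequence that occurs once. X held 276 tRNA genes, of which 74 had a peak (26.8%, 21.9 to 32.3), against 73 of 336 on autosomes (21.7%, 17.6 to 26.4).

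The highest tRNA gene peak, at X:3035907-3036376 (signal 484), lay at a tRNA-Gly gene (WBGene00023110) and a tRNA-Glu gene (WBGene00023111). The next lay at a tRNA-Ala gene (WBGene00014333) at X:9743580-9743814, with a signal of 478. Their sequences occur 29, 20 and 8 times in the genome, so reads inside them cannot be assigned to a copy by sequence alone. Among snoRNA genes the highest peaks were near F54E7.10 (III:5679015-5679245, signal 526, the ska-3 promoter peak) and at the neighbouring C51F7.3 and C51F7.4 (V:12303408-12303877, signal 416). Among snRNA genes they were at sls-2.1 (signal 656), sls-2.4 (signal 610) and sls-2.2 (signal 483), each with a sequence that occurs once.

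Ribosomal protein, splicing factor, respiratory chain, heat shock and translation factor genes had promoter peaks more often than other genes. Of 19973 protein-coding genes, 898 (4.50%) had one, against 2.00% in shifts. Cytosolic ribosomal protein genes had a peak in 36 of 76 cases (47.4%, 95% interval 36.5 to 58.4; Fisher's exact test, adjusted p = 3.58e-27), led by rpl-3, rpl-15, rpl-35 and rpl-20. Splicing factor genes had one in 7 of 21 (33.3%, Fisher's exact test, adjusted p = 0.000121), including snr-4 (signal 266), rsp-2, prp-8 and snr-1. Respiratory chain genes had one in 10 of 35 (28.6%, Fisher's exact test, adjusted p = 1.41e-05), with cox-5A (signal 452) and cox-5B (signal 386), both of cytochrome c oxidase, ahead of ucr-2.2 and atp-1.

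Heat shock protein genes had a peak in 5 of 22 (22.7%, Fisher's exact test, adjusted p = 0.00842), among them the chaperone genes hsp-1 (signal 470), hsp-90 (signal 364), hsp-3 and hsp-110, the last sharing its peak with the proteasome gene rpn-3. Translation factor genes had one in 8 of 38 (21.1%, Fisher's exact test, adjusted p = 0.000951), led by the elongation factor genes eef-1A.2 (signal 395), eef-1G (signal 255) and eef-2 (signal 249) and by eif-3.C (signal 247). The 5 lists also exceeded circular shifts (adjusted permutation p = 0.00799 for each). That compares them with random placement and not with other genes, since all protein-coding genes exceeded shifts too (4.50% against 2.00%). When only the genes with a promoter entry in the pooled unthresholded list served as background, the ribosomal protein list alone passed Fisher's exact test, and the adjusted p was 0.144 for splicing and respiratory chain genes, 0.605 for heat shock and 0.858 for translation factors. With a 250 bp window, ribosomal protein genes had a peak in 9 of 76 cases (11.8%; exact test, adjusted p = 0.00279), below splicing (19.0%), respiratory chain (17.1%) and translation factor genes (13.2%), which also passed, while heat shock genes (9.09%, adjusted p = 0.286) did not. Among the stricter part of the peaks splicing genes (9.52%; exact test, adjusted p = 0.236) did not pass, and respiratory chain genes had 11.4%. In the list without replicate 2, respiratory chain genes had a peak in 6 of 35 (17.1%; exact test, adjusted p = 0.0127).

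**Figure D4:**
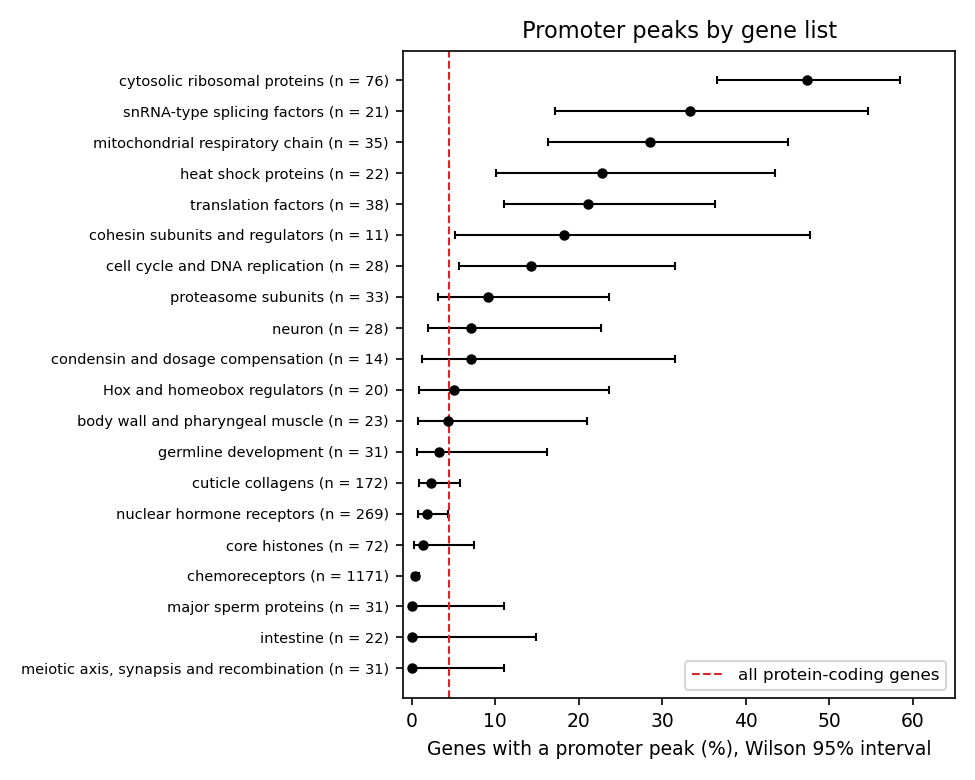
Share of genes in each list with a promoter peak (x axis, %) and its Wilson 95% interval, 1 row per list (y axis) with the number of genes; the dashed line is the share of all 19973 protein-coding genes, 4.50%. The ribosomal protein list is highest at 47.4%.

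Chemoreceptor genes, which act in sensory neurons, had a peak in 4 of 1171 cases (0.342%, 95% interval 0.133 to 0.875), below the 4.75% of other genes (Fisher's exact test, adjusted p = 8.73e-18; adjusted permutation p = 0.0114 by shifts). Among them were sri-5 (signal 273), srh-16 (signal 190) and sri-18 (signal 111). With the background limited to genes in the pooled unthresholded list the chemoreceptor share was 10.5% and did not pass the same exact test (adjusted p = 0.278). The share was 0.171% with a 250 bp window, 0.598% with 1000 bp and 0.512% without replicate 1, each below other genes by the test. Cell cycle genes had a peak in 4 of 28 (14.3%), namely pcn-1 (PCNA, signal 266), lin-35 (the Rb homologue, signal 173), cdk-4 and cdc-6. This share passed by circular shifts (adjusted permutation p = 0.0114), which compare it with random placement. It did not pass against other genes by Fisher's exact test (adjusted p = 0.0906). With a 250 bp window it was 2 of 28 (7.14%; exact test, adjusted p = 0.344).

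Among cohesin genes, promoter peaks were found at smc-3 (signal 132), which encodes the partner of HIM-1, and wapl-1 (signal 137), a cohesin release factor, and not at coh-1, coh-3, coh-4, evl-14, him-1, mau-2, rec-8, scc-1 or scc-3 (2 of 11; Fisher's exact test, adjusted p = 0.189). The symbols coh-2 and pqn-85 of this list were not matched to the annotation, so no peak was looked up under them. In the condensin and dosage compensation list 1 of 14 genes had a peak, sdc-2 (signal 138), which directs dosage compensation to X (exact test, adjusted p = 0.594); without replicate 1 it was 2 of 14 (14.3%). Proteasome genes had one in 3 of 33, at rpn-3, rpn-11 and rpn-13 (exact test, adjusted p = 0.359). None of the 31 meiosis genes or the 31 major sperm protein genes had one (exact test, adjusted p = 0.535 for each), nor did the 22 intestine genes (adjusted p = 0.693).

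The remaining lists did not pass the test either. By Fisher's exact test, germline development had 1 of 31 (nos-3, adjusted p = 1), muscle 1 of 23 (unc-60, adjusted p = 1), core histones 1 of 72 (his-37, adjusted p = 0.535) and homeobox genes 1 of 20 (unc-62, adjusted p = 0.693). Neuron genes had 2 of 28 (egl-21 and rab-3; exact test, adjusted p = 0.535), and cuticle collagens 4 of 172 (col-85, col-72, col-71 and col-38, adjusted p = 0.359). Nuclear hormone receptors had 5 of 269 (1.86%; exact test, adjusted p = 0.0906), the highest at nhr-1, nhr-40, nhr-47 and nhr-49. These small counts moved when a replicate was left out: core histones had 3 of 72 (4.17%) without replicate 1, germline development 0 of 31 without replicate 2, homeobox genes 0 of 20 without replicate 1 and neuron genes 1 of 28 (3.57%) without either. With a 250 bp window collagens and muscle genes had none and nuclear hormone receptors 1.12%, with 1000 bp the last had 2.97% and core histones 2.78%, and among the stricter part of the peaks proteasome genes had 3.03%, collagens 1.16% and germline development none.

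Sequence at the summits was rich in GC and in several fixed motifs. The median GC content within 100 bp of the summit was 45.8%, against 35.1% in circular shifts. A tRNA B box (GGTTCGANNCC) lay within 100 bp of 86 summits (4.79%, against 0.308% in shifts), the MEX motif of dosage compensation recruitment sites (TCGCGCAGGGAG, up to 3 mismatches) of 293 (16.3% against 3.89%), and a GAGA repeat (GAGAGAGAGA) of 132 (7.35% against 0.535%). Sp1-like (11.2% against 3.19%) and E2F-like sites (6.34% against 3.17%) were also enriched, while GATA sites were depleted (11.7% against 27%). All of these had an adjusted permutation p of 0.00257, and the E-box (4.06% against 3.36%, adjusted permutation p = 0.117) and CRE (1.56% against 1.15%, adjusted permutation p = 0.150) did not pass. The E-box passed with the stricter peaks (5.35%, adjusted permutation p = 0.00674), without replicate 2 (4.40%, adjusted permutation p = 0.00899) and within 50 bp (2.73%, adjusted permutation p = 0.00450), and CRE without replicate 2 (1.73%, adjusted permutation p = 0.0260).

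Against random positions matched on GC content, a comparison chosen after seeing the data, the random mean of MEX was 9.07%, and those of the B box (0.635%), GAGA repeat (1.14%), Sp1-like (7.40%) and E2F-like (4.33%) sites also stayed below the shares at peaks, while that of GATA sites (17.2%) stayed above (adjusted permutation p = 0.00300 for each). The E-box was then lower at peaks than at matched positions (5.39%, adjusted permutation p = 0.0154). On X the B box lay at 9.61% of summits and MEX at 19.7%, against 3.38% and 15.3% on autosomes; these differences were not tested.

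Neither the him-1 nor the unc-119 locus stood out in the optimal list. Within 20 kb of him-1 (I:4951571-4957667) there were 2 optimal peaks, the higher with a signal of 178, and none within 5 kb; 79.8% of protein-coding genes had fewer in a window of the same size and 91.6% had as many or fewer. Within 20 kb of unc-119 (III:10902641-10908935), a gene often used to select worm transgenes, there was no optimal peak, as for 56.7% of genes. In the pooled unthresholded list him-1 had 13 entries within 20 kb, more than 93.1% of genes, and unc-119 had 7, more than 68.6% of genes, but within 5 kb both had 5 (more than 89.7% and 89.5% of genes). Within 20 kb in the list of replicate 2, him-1 had 10 entries and unc-119 had 11 (more than 75.9% and 80.9% of genes).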

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

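Of 303 recomputed values for 49 results, 265 kept their direction and any side of a threshold, or a count within 1.5 times, 8 lost the threshold, 7 gained it, 19 reversed and 4 counts moved by more. The alternatives without tRNA or snoRNA gene peaks, with single-copy genes and with GC-matched positions were chosen after seeing the data. Replicate overlap, centre density over all chromosomes, feature shares and non-coding RNA genes kept direction and side of the threshold under every alternative run, though shares moved with the window, and the replicate correlation, which has no test, stayed positive. By chromosome, the centre ratio fell below 1 on IV per protein-coding gene (0.977) and rose above 1 on X without replicate 1 (1.04). Depth is unknown and limits all results. No paired analysis was possible because there was a single group.

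The test of bin medians for X and autosomal signal passed with the stricter peaks and 1 Mb bins. The log2 differences of peak medians there were 0.16 and 0.10. Over the lists without replicate 1 or 2 that difference was 0.10 to 0.11, and the bin test passed without replicate 1. The bin test did not pass without replicate 2 or with the ce10 lists. X density without tRNA gene peaks was 1.19 times that of autosomes and no longer passed. With genes of the pooled list as background, 1 gene list exceeded other genes and 0 lay below. Fewer genes were compared there, and odds ratios also moved towards 1. They fell from 19.9 to 4.77 for ribosomal protein, 10.7 to 3.61 for splicing and 8.58 to 2.82 for respiratory chain genes. For heat shock genes the fall was from 6.28 to 2.21 and for translation factors from 5.71 to 1.65, while chemoreceptors rose from 0.0687 to 0.360. With GC-matched positions 2 motifs lay below random positions, and the E-box (4.06%) reversed; it gained the threshold with stricter peaks, a 50 bp window and without replicate 2, and CRE without replicate 2. Within 5 kb of him-1 there were 0 peaks. The cause was not tested.

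Several lists that passed no test changed side of the other genes' share. With stricter peaks these were cohesin, condensin and homeobox (0% each) and muscle (4.35%). Over the lists without replicate 1 or 2, neuron was 3.57% in both and changed side in both; homeobox was 0% to 5% and changed side without replicate 1 only; muscle was 4.35% in both and changed side without replicate 2 only. With a 250 bp promoter they were condensin (0%) and germline (3.23%), and with 1000 bp muscle (8.70%) and homeobox (5%). With the pooled background they were germline (25%), proteasome (21.4%), muscle (33.3%), collagens (50%) and neuron (20%). Muscle was 4.35% without tRNA or snoRNA gene peaks. The cause was not tested.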

Other observations

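Tests of the MEX motif on X with up to 2 mismatches, of X density without MEX peaks and of gene lists taken as highly transcribed were chosen only after the results they bear on were seen. X peaks with the MEX motif had a higher median signal than other X peaks. The limit of 2 mismatches was set after results were seen, so p-values that use it may overstate the evidence. Of 406 X summits, 25 (6.16%, 95% interval 4.21 to 8.93) had MEX with up to 2 mismatches within 100 bp, and their median signal was 447, against 150.2 for the other X peaks, a log2 difference of 1.57 (permutation p = 5e-05, the smallest the 20000 permutations can give). On autosomes 22 of 1391 summits had it, with a log2 difference of 0.05 (permutation p = 0.701). Of the 15 X peaks among the 25 highest, 11 had the motif with up to 2 mismatches. It was exact at the peaks nearest W02H3.3 and Y41G9A.17, and had 1 mismatch at the one upstream of xol-1. None of the 10 autosomal peaks among the 25 highest had it even with up to 3 mismatches.

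Within X, GC content was argued against as the cause of the higher signal of MEX peaks. The 25 MEX peaks exceeded X peaks without MEX of like GC by 1.65 in median log2 signal, above the highest of 1000 draws. Their median GC was 42.8%, against 48.3% at the other X summits. X and autosomal peaks were not matched on GC, so GC content stays open for the share of X among the highest signals. The motif lay at 25 X summits against a mean of 1.12 in circular shifts, a 15.7-fold enrichment with 0.5 added to both counts, while 100 column-shuffled versions reached at most 8.77-fold by the same formula. These values are consistent with a hypothesis that sites of dosage compensation recruitment are among the strongest HIM-1-eGFP peaks on X. Whether HIM-1 binds there or such sites come down in any immunoprecipitation stays open, since no untagged control was analysed here, and the design has no group that tests biology.

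For the excess of peaks on X, MEX sites with up to 2 mismatches were too few to be the whole cause, since 25 of 406 X peaks had one. The ratio to autosomes without them was 1.3 (95% bootstrap interval 1.15 to 1.47, permutation p = 0.0139). That ratio follows largely from the count and is no independent test. The many tRNA genes on X may account for part of it, since without tRNA gene peaks the ratio was 1.19 with an interval of 1.02 to 1.38, which spans both outcomes. Scaling of the whole chromosome, for example by the control, also stays open: promoter peaks per protein-coding gene were 1.37 times as frequent on X (1.1 to 1.67, permutation p = 0.0105). Per Mb, a comparison added after seeing the data, promoter peaks had a ratio of 1.01 (0.807 to 1.23, permutation p = 0.909). Other peaks had 1.65 (1.38 to 1.97, permutation p = 0.00033). Promoter windows held a mean of 18.7% of circularly shifted summits on X, against 23.6% on autosomes. A ratio of 1.01 per Mb therefore does not exclude an excess at X promoters. The tRNA gene and scaling explanations cannot be told apart with these intervals.

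For the peaks at tRNA genes, reads shared between copies stay open as a cause. Genes whose full sequence occurs once can still share shorter stretches with similar genes. A summit within 250 bp can also belong to a neighbouring tRNA gene, so the shares below do not decide it. Of 140 tRNA genes whose sequence occurs once, 15% had a peak (95% interval 10 to 21.8), above the highest of 1000 shifts, 4.29%; among the 472 with further copies the share was 26.7% (22.9 to 30.9). Antibody background at highly transcribed genes could also give such peaks and cannot be told apart from binding without an untagged immunoprecipitation. Ribosomal protein genes had a promoter peak in 47.4% of cases, as that background would need. The intestine, muscle, collagen and sperm protein lists together had one in 5 of 248 (2.02%), against 4.53% of other genes (Fisher's exact test, p = 0.0623). Of the 248 genes, 172 were cuticle collagens. How strongly these lists are transcribed here was not measured, so they decide nothing about that background.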
